A study of Rattus norvegicus with 18 samples.

How the data were processed

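Total RNA from the right liver lobe of Sprague-Dawley rats was hybridised to Affymetrix rat whole-genome expression arrays, which hold 31099 probe sets. Per the labels, RNA was extracted with Trizol and RNeasy columns, 5 ug was labelled per array, and 3 arrays were run for normal liver and for each of 5 times of diethylnitrosamine treatment (18 arrays). Per the submitters' processing notes the arrays were processed with GCOS 2.0. The scaling target, the dose and the sex are not given in the sources used here. The deposited value table holds a summary intensity per probe set and array on a linear scale, scaled between arrays by the authors. A deposited workbook holds the same intensity values rounded to 1 decimal. It also holds, per the file headers, a log2 ratio of each treated array to each normal array (9 pairs of arrays per time). The deposited ratio columns equal 2 to the power of these log2 ratios, within 1 percent in 100% of the values.

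The workbook's 15 treated columns were checked against the value table and equalled it within 0.11. Its 3 normal columns held the same values in another order, since sorted values were equal in 100% of cases while the correlation by probe set was at most 0.127, so these columns were left out. The authors gave no detection calls, so no gene is given as a bound. The sum of signals per array ranged from 2.23e+07 to 2.64e+07, and the number of arrays limits the precision.

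Signals were transformed to log2(signal + 16) with no further scaling between arrays. The pseudocount of 16 keeps low signals from giving large fold changes and understates the fold change of weakly expressed genes. Probe sets with a mean above the percentile of 40 over all arrays were kept (signal of 87.5, 18625 probe sets). Of all probe sets 57 were controls, 23 named several genes, 11121 had no gene name and 19898 named 1 gene (13902 genes). Names came from the reference accession for 3076, a current symbol for 12357, a synonym for 2986, and the deposited symbol alone for 1479. For each gene the probe set with the highest mean was tested, which left 10452 genes.

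The 6 groups were fitted together in limma 3.58.1 under R 4.3.3, with contrasts of each time with normal liver, of each time with the time before it and of the mean of the treated groups with normal liver. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 and a fold change of at least 2, and all tests were two-sided. A moderated F-test covered the 6 groups, and a slope over weeks was fitted to the 6 group means. Of 41 gene lists 39 had at least 5 measured genes and were tested with camera in limma at a preset correlation of 0.01, with p values adjusted over 195 tests against normal liver and over 156 tests against the previous time. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

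Named genes followed a rule. For each time against normal liver it took the 6 genes with the highest and the 6 with the lowest change whose 3 arrays all lay on 1 side of the 3 normal arrays, leaving out provisional symbols, and for each step the 3 highest and 3 lowest. For each list it took up to 4 called members with the largest mean change and members that went against the list, plus a short set fixed by name, which gave 200 genes. Of these genes 43 had another probe set above the filter (56 probe sets), of which 0 were called in the opposite direction and 11 shared no call with the tested one, for example those of Mx2, RT1-N3 and Jun.

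The pipeline was tested on simulated data with the layout and spread of the real arrays, in which 200 of 10452 genes were changed. For 16 weeks against normal liver it called 96 of 100 genes changed by 1.5 on the log2 scale and 100 of 100 changed by 2.5, with 1 false call, and for 18 against 16 weeks 98 of 100 and 99 of 100, with 1 false call. For the lists, 25 of 25 tests of lists shifted by 0.5 on the log2 scale were recovered, with 1 false call in 160 tests. The simulated noise was independent between genes, so false calls that come from correlated genes in a list were not covered. Alternatives tried were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a stricter one, every probe set, the mean of a gene's probe sets, no fold threshold and one of 3, a trended and robust variance, fits of only the groups compared, a replicate block, each array left out in turn, an estimated correlation for the lists, and other forms of the trend. The use of time means in place of arrays, of the authors' deposited log2 ratios, of the times without 8 weeks, and of 5 weeks as the reference was chosen after the data were seen.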

Results

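Rat liver was profiled on Affymetrix rat whole-genome expression arrays in normal Sprague-Dawley rats and after 5, 8, 12, 16 or 18 weeks on diethylnitrosamine, a nitrosamine that alkylates DNA after activation by cytochrome P450 enzymes and is given to rodents to produce liver tumours. Each of the 6 groups had 3 arrays. The labels call the 3 arrays of a group technical replicates, so the p values measure only the spread between arrays, which may be technical and hold no difference between animals. Normal liver was sampled at 0 h alone, with no untreated liver of matching age, and the labels give an age of 12 weeks for every sample, so time on treatment was not separated from age. The comparisons, the gene lists and the rule for naming genes were set before the data were examined. Values below are log2 fold changes ± SE from limma (n = 3 arrays per group) against normal liver unless another reference is given, signals are mean ± SD on the deposited scale (n = 3), and adjusted p values come from limma. Where the signal of a group lay below 87.5, the level of the filter on genes, the size of a change depends on the pseudocount of 16 and is no exact fold, as for Adam8, Fabp4, Lama5, Bex1, Aldh3a1, Ddit4l, Pcp4, Abcc3, Mcpt2 and Aqp5 in normal liver, Cpa1 at 5 weeks and Mx2 at 16 weeks. Saturation of the brightest probe sets, with signals above 14196 (99 percent of probe sets in normal liver lay below it), was not tested, and changes that involve such signals may be understated, as for A1bg, Akr1b7, Sult2a2, Cyp2c11 and Car3 in normal liver and Akr1b8 and Gstp1 at 12 to 18 weeks.

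Liver moved away from normal at every time, with 635 of 10452 genes changed at 5 weeks, 1091 at 8 weeks, 1725 at 12 weeks, 2100 at 16 weeks and 1612 at 18 weeks. Of the 2736 genes changed at 1 time or more, 979 lay furthest above normal and 360 furthest below it at 16 weeks. The stress and tumour-associated genes Cdkn1a, Gstp1 and Aldh3a1 rose, the proliferation gene Cdk1 and the collagen gene Col1a1 rose, and the hepatocyte genes Cyp2c11 and Cyp7a1 fell at the later times. Arrays of 1 group correlated over genes at r = 0.985 to 0.991 and arrays of different groups at r = 0.875 to 0.980, where genes are not independent replicates. The median SD of log2 signal was 0.12 within a group and 0.23 between the 5 treated means. The median signal of an array was 126 ± 3.72 in normal liver and 136, 137, 169, 180 and 145 from 5 to 18 weeks. As deposited, the median change of all genes was 0.04, 0.12, 0.15, 0.16 and 0.11 from 5 to 18 weeks, and the changes below can be read relative to it. Centring every array on its median shifted this median to -0.06, 0.01, -0.23, -0.31 and -0.07.

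**Figure D1:**
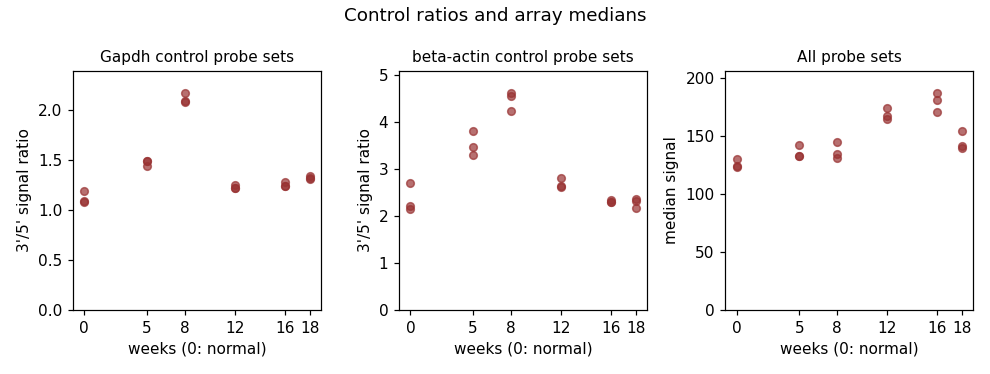
Ratio of 3' to 5' probe sets of Gapdh and of beta-actin, and median signal of all probe sets (deposited scale), for each of the 18 arrays by group. Gapdh ratios averaged 1.12 in normal liver and 2.12 at 8 weeks, and median signals averaged 126 in normal liver and 180.1 at 16 weeks.

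Control probe sets for RNA integrity varied between groups. The Gapdh 3'/5' ratio, which increases when transcripts are shortened, averaged 1.12 ± 0.0599 in normal liver, 1.48 ± 0.0293 at 5 weeks, 2.12 ± 0.0521 at 8 weeks, 1.23 ± 0.0185 at 12 weeks, 1.26 ± 0.0219 at 16 weeks and 1.32 ± 0.0134 at 18 weeks. The beta-actin 3'/5' ratio averaged 2.36 ± 0.305 in normal liver, 3.52 ± 0.260 at 5 weeks, 4.48 ± 0.203 at 8 weeks and 2.29 to 2.69 at the later times. Other control probe sets also set normal liver apart. The poly-A control dap had a signal of 5776 ± 493 in normal liver and 3895, 3567, 3228, 2588 and 3057 from 5 to 18 weeks. The control cre had 35325 ± 4572 in normal liver and 25730 to 32104 in the treated groups. The cause was not tested. The members of the fixed housekeeping list, such as Gapdh and Actb, did not pass as a list of 15 against normal liver at any time and had medians of -0.05, -0.05, 0.09, -0.06 and 0.11 from 5 to 18 weeks. Against the previous time this list passed at every step, with medians of -0.13, 0.30, -0.10 and 0.14 (adjusted p = 0.0107, 0.0216, 0.0283 and 0.0418, camera in limma). With an estimated correlation it passed at no step (adjusted p = 0.254, 0.3, 0.314 and 0.348). Small shifts of other lists between times can be read against these control genes. Counts of list members were the same when adjusted over the list alone, apart from 7 circadian clock genes at 5 weeks, 5 acute phase genes at 12 weeks and 3 at 8 against 5 weeks, and 5 mast cell genes at 12 against 8 weeks and 1 at 16 against 12 weeks.

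At 5 weeks of treatment, p53 target genes, mitotic genes and matrix genes were higher than in normal liver. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 4.72 ± 0.121, from a signal of 244 ± 61.8 to 6684 ± 70.1. The metalloprotease gene Adam8 rose by 5.14 ± 0.141, the laminin gene Lama5 by 3.69 ± 0.135, and Fabp4, which encodes a fatty acid binding protein of adipocytes and macrophages, by 3.80 ± 0.361. Tmem14a (3.74 ± 0.139) and Vxn (3.53 ± 0.0765) were the other genes among the 6 with the largest rise. Among the largest falls were those of Cpa1, which encodes the pancreatic enzyme carboxypeptidase A (-7.28 ± 0.331), A1bg (-7.17 ± 0.115), Akr1b7 (-7.12 ± 0.0439), the sulfotransferase gene Sult2a2 (-4.70 ± 0.0651) and the prolactin receptor gene Prlr (-3.99 ± 0.0808). The rule that picked these genes required all 3 treated arrays to lie on 1 side of all 3 normal arrays.

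By list, 8 of 16 DNA damage response and p53 targets rose at 5 weeks and 1 fell, with a median change of 0.98 (adjusted p = 1.58e-05, camera in limma). Btg2, an antiproliferative gene, rose by 1.81 ± 0.0941, the p53 ubiquitin ligase gene Mdm2 by 1.04 ± 0.0466 (other probe sets at 0.19 and 0.96) and the DNA repair methyltransferase gene Mgmt by 1.40 ± 0.0445, while the sestrin gene Sesn1 fell (-1.07 ± 0.113). Among mitosis and G2/M genes 14 of 20 rose (adjusted p = 1.75e-09), including cyclin A2 (Ccna2, 1.98 ± 0.129), the kinesin gene Kif2c (2.28 ± 0.0938), Cdk1 (1.88 ± 0.117) and Mki67 (1.5 ± 0.0669). G1/S and replication genes had 4 of 23 up (adjusted p = 0.0018), with the ribonucleotide reductase gene Rrm2 at 2.39 ± 0.0573 (another probe set at 0.94) and cyclin D1 (Ccnd1) at 1.47 ± 0.103 (others at 0.77 and 1.04). Of 26 extracellular matrix genes 11 rose (adjusted p = 5.93e-10), among them Col1a1 (1.56 ± 0.0872, with another probe set at 0.34), Col4a2 (1.87 ± 0.159) and Loxl1 (1.65 ± 0.219), whose product crosslinks elastin, and stellate cell and myofibroblast markers shifted up with 0 of 12 past the threshold (median 0.49, adjusted p = 0.00855). The cytokine gene Tgfb1 rose by 3.46 ± 0.152 in a list of TGF-beta genes with 3 of 13 up (adjusted p = 0.0426, adjusted p = 0.2 with an estimated correlation).

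Antigen presentation genes were also higher at 5 weeks, with 6 of 7 MHC class II genes up (adjusted p = 2.12e-05), including Cd74 (1.79 ± 0.0548) and RT1-Bb (2.0 ± 0.0394). In the preneoplastic marker list 8 of 18 genes rose and 1 fell (adjusted p = 0.00128), and Gstp1, the placental glutathione transferase used to stain preneoplastic foci in rat liver, rose by 1.64 ± 0.0559. Of 17 NRF2 antioxidant targets 2 rose at 5 weeks, with a median of 0.31 (adjusted p = 0.00661, adjusted p = 0.0729 with an estimated correlation), including Gclc (1.14 ± 0.0476, with another probe set at 0.66). Lists of hepatocyte metabolism differed. Conjugating enzymes (median 0.10, adjusted p = 0.375) and fatty acid oxidation (median -0.03, adjusted p = 0.45) did not pass. Lipogenesis and cholesterol synthesis had a median of -0.62 with 4 of 24 down (adjusted p = 1.92e-06), bile acid genes -0.42 with 1 of 19 down (adjusted p = 0.0001), and urea cycle and amino acid catabolism -0.29 with 3 of 27 down (adjusted p = 2.47e-09). Hnf4a, a master regulator of hepatocyte identity, fell (-1.98 ± 0.0672, with another probe set at -1.09), and albumin (Alb) had a change of -0.39 ± 0.109, below the 2-fold threshold. Of 9 genes listed, after their values were seen, as expressed mainly in female rat liver, 7 fell at 5 weeks, among them A1bg, Akr1b7, Prlr and Sult2a2, and all 9 were higher in every normal array than in every treated array. None of 6 genes expressed mainly in male rat liver passed the test at 5 weeks, with Cyp2c11 at 0.04 ± 0.131, and 4 of these 6 were brighter than 99 percent of probe sets. The labels give no sex. In the exocrine pancreas list 3 of 5 genes fell at 5 weeks (adjusted p = 0.0622), with Cpa1 at a signal of 6264 ± 251 in normal liver and 24.6 ± 5.13 at 5 weeks. With a pseudocount of 64 in place of 16 the count at 5 weeks was 402 genes, and after median centring 61.2% of the calls were up against 73.5% as deposited.

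At 8 weeks genes of the antioxidant response stood higher than at 5 weeks. The aldo-keto reductase gene Akr1b8 rose by 4.89 ± 0.103 and Aldh3a1, an aldehyde dehydrogenase of detoxification, by 4.32 ± 0.215, from a signal of 25.8 ± 18.0, below the filter, to 775 ± 76.2. Bex1 rose by 5.25 ± 0.308, with another probe set of this gene at 1.41, Adam8 by 5.29 ± 0.141, Cdkn1a by 4.58 ± 0.121 and Lama5 by 4.48 ± 0.135. Cpa1 (-6.75 ± 0.331), A1bg (-6.36 ± 0.115), Akr1b7 (-6.11 ± 0.0439), Prlr (-5.10 ± 0.0808) and Cd14, which encodes a receptor for bacterial lipopolysaccharide (-4.32 ± 0.0706), were among the genes with the largest falls. In all, 764 genes rose and 327 fell.

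Of 17 NRF2 antioxidant targets 9 rose at 8 weeks, with a median of 1.05 (adjusted p = 4.38e-07), including the cystine transporter gene Slc7a11 (2.53 ± 0.186), the sulfiredoxin gene Srxn1 (2.18 ± 0.0881, with another probe set at -0.14) and Gclc (1.98 ± 0.0476), the catalytic subunit of the rate-limiting step of glutathione synthesis. In the preneoplastic marker list 10 of 18 rose and 1 fell (adjusted p = 9.42e-05), with Gstp1 at 3.68 ± 0.0559 and the aflatoxin reductase gene Akr7a3 at 3.41 ± 0.0584. The member that fell was the neutrophil lipocalin gene Lcn2 (-1.80 ± 0.128). Mitotic genes had 17 of 20 up (adjusted p = 2.6e-08), with Kif2c at 2.71 ± 0.0938 and Melk at 1.97 ± 0.325. Matrix genes had 15 of 26 up (adjusted p = 1.43e-07), with Loxl1 at 2.64 ± 0.219 and Col1a1 at 2.27 ± 0.0872 (another probe set at 1.01), and stellate cell and myofibroblast markers 3 of 12 (adjusted p = 0.0091). Cholangiocyte and progenitor markers had 6 of 11 up (adjusted p = 0.00142), among them the transcription factor gene Sox4 (2.94 ± 0.0484, with other probe sets at 0.22, 0.72 and 1.92) and the tight junction gene Cldn7 (2.54 ± 0.146). MHC class II genes had 6 of 7 up (adjusted p = 0.00027), with RT1-Db1 at 2.26 ± 0.0704.

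Several hepatocyte lists lay below normal at 8 weeks, while conjugating enzymes, with 2 up and 0 down of 20, did not pass (adjusted p = 0.282), and fatty acid oxidation had a median of -0.24 (adjusted p = 0.0014, adjusted p = 0.11 with an estimated correlation). Urea cycle and amino acid catabolism had a median of -0.66 with 4 of 27 down (adjusted p = 2.6e-14), including the lysine catabolism gene Aass (-1.51 ± 0.0597). Lipogenesis and cholesterol synthesis had 9 of 24 down (adjusted p = 1.7e-08), with the fatty acid elongase gene Elovl5 at -2.47 ± 0.0730. Among 23 hepatocyte transcription factors and secreted proteins 3 fell (adjusted p = 1.19e-08). These were Hnf4a (-2.91 ± 0.0672, with another probe set at -1.78), Nr5a2 (-2.28 ± 0.0886) and Onecut1 (-1.79 ± 0.0798, with another probe set at -1.19). Complement and coagulation had 1 of 22 down (adjusted p = 9.27e-12), and the acute phase list had 3 of 21 down (adjusted p = 2.15e-09). The Gapdh and beta-actin 3'/5' ratios were highest at this time, at 2.12 and 4.48, and these lists were measured on arrays that stood apart from the others in that respect. With 8 weeks left out, 390 genes were called in 1 direction at the 4 other times. After median centring 59.6% of the calls at 8 weeks were up, against 70.0% as deposited.

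By 12 weeks NRF2 targets had risen further, and bile acid and cytochrome P450 genes had fallen further. Aldh3a1 rose by 7.21 ± 0.215, to a signal of 5795 ± 217, Bex1 by 7.01 ± 0.308 (another probe set at 1.72), Akr1b8 by 6.95 ± 0.103, Ddit4l by 6.12 ± 0.269, Pcp4, which encodes a calmodulin-binding peptide of neurons, by 5.92 ± 0.215, and Abcc3, an organic anion exporter of the basolateral membrane, by 5.47 ± 0.307. Among the largest falls were those of A1bg (-6.34 ± 0.115), Obp3 (-6.27 ± 0.122), Cpa1 (-5.90 ± 0.331), Cyp3a9 (-4.67 ± 0.0656) and Cyp2c11, the main cytochrome P450 of adult male rat liver (-4.90 ± 0.131). Of 10452 genes 1262 rose and 463 fell.

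All but 2 of 17 NRF2 antioxidant targets rose at 12 weeks (15 genes, median 2.02, adjusted p = 2.41e-10), with Srxn1 at 3.91 ± 0.0881 and Gclc at 3.45 ± 0.0476. In the preneoplastic marker list 15 of 18 rose (adjusted p = 5.26e-08), with Gstp1 at 4.59 ± 0.0559, the gamma-glutamyltransferase gene Ggt1, a marker of foci, at 3.87 ± 0.145 and the fetal growth factor gene Igf2 at 2.20 ± 0.432. The fetal protein gene Afp had a change of 0.67 ± 0.0612, which did not pass. Every one of the 20 mitotic genes rose (adjusted p = 1.01e-07), with Ccna2 at 2.96 ± 0.129 and Cdk1 at 2.44 ± 0.117. Matrix genes had 20 of 26 up (adjusted p = 1.67e-07), with Col1a1 at 3.81 ± 0.0872 (another probe set at 2.44) and decorin (Dcn) at 2.46 ± 0.0603, and stellate cell and myofibroblast markers 5 of 12 (adjusted p = 0.00456). Cholangiocyte and progenitor markers had a median of 2.61 with 9 of 11 up (adjusted p = 3.29e-06), among them Cd24 (3.79 ± 0.0870) and the bile duct keratin gene Krt19 (2.94 ± 0.142). Mast cell markers had 5 of 6 up (adjusted p = 0.0214), with the protease genes Mcpt2 at 5.18 ± 0.335 and Cma1 at 3.38 ± 0.439. Glycolysis genes had 4 of 16 up (adjusted p = 0.0218, adjusted p = 0.0619 with an estimated correlation), with hexokinase 1 (Hk1) at 2.01 ± 0.136.

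Lower lists at 12 weeks covered most hepatocyte functions. Of 22 drug-metabolising cytochrome P450 genes 13 fell and 1 rose, with a median of -1.16 (adjusted p = 6.34e-12). Cyp1a2, a P450 of centrilobular hepatocytes, fell (-3.55 ± 0.0769), and Cyp1a1, which is induced through the aryl hydrocarbon receptor, rose (3.60 ± 0.138). Bile acid synthesis and transport had 11 of 19 down (adjusted p = 3.93e-07), including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.23 ± 0.0713), and the bile acid uptake transporter gene Slc10a1 (-2.18 ± 0.0503). Urea cycle and amino acid catabolism had 15 of 27 down (adjusted p = 2.55e-17), with the glycine methyltransferase gene Gnmt at -2.33 ± 0.0618. Fatty acid oxidation had 8 of 20 down (adjusted p = 7.02e-08), with Pdk4 at -2.52 ± 0.166 and Cpt1a, the entry step of mitochondrial oxidation, at -1.91 ± 0.0772. Gluconeogenesis and glucose handling had 5 of 14 down (adjusted p = 1.4e-07), with the glucose-6-phosphatase gene G6pc1 at -2.35 ± 0.0696. Complement and coagulation had 10 of 22 down (adjusted p = 2.74e-14), with the mannose-binding lectin gene Mbl2 at -2.08 ± 0.0504. Pericentral Wnt targets had 5 of 10 down (adjusted p = 7.39e-05), with the ornithine aminotransferase gene Oat at -3.06 ± 0.119. The acute phase list had 3 genes down and 1 up of 21 (5 adjusted over the list alone, adjusted p = 7.28e-05, adjusted p = 0.162 with an estimated correlation). The direction split depended on scaling, since median centring gave 706 genes up and 1057 down (40.1% up) in place of 73.2% up.

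The number of genes changed against normal liver was highest at 16 weeks, with 1515 genes up and 585 down. Bex1 rose by 6.68 ± 0.308 (another probe set at 1.83), Akr1b8 by 6.61 ± 0.103, the mast cell protease gene Mcpt2 by 5.57 ± 0.335, Ddit4l by 5.24 ± 0.269, Aldh3a1 by 5.10 ± 0.215 and Aqp5, a water channel of secretory epithelia, by 5.01 ± 0.373. Obp3 (-6.93 ± 0.122), Cyp2c11 (-6.74 ± 0.131), Cpa1 (-5.15 ± 0.331), A1bg (-4.62 ± 0.115), the interferon-induced GTPase gene Mx2 (-4.40 ± 0.149) and the carbonic anhydrase gene Car3 (-4.40 ± 0.0708) had the largest falls. The Cyp2c11 signal was 20718 ± 708 in normal liver and 179 ± 13.8 at 16 weeks. The median signal of an array was also highest at this time, at 180.1 against 126 in normal liver.

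Cholangiocyte and progenitor markers had the highest list median at 16 weeks, 3.83, with 10 of 11 up (adjusted p = 2.03e-06). Examples are Cd24 (4.49 ± 0.0870), Cldn7 (4.26 ± 0.146) and Krt19 (4.15 ± 0.142). Preneoplastic markers had 16 of 18 up (adjusted p = 1.18e-07), with Gstp1 at 4.23 ± 0.0559, Ggt1 at 3.31 ± 0.145 and Afp at 1.01 ± 0.0612. Matrix genes had 21 of 26 up (adjusted p = 2.95e-08), with Loxl1 at 4.30 ± 0.219 and Col1a1 at 3.87 ± 0.0872 (another probe set at 2.13), and stellate cell and myofibroblast markers 9 of 12 up (adjusted p = 0.000645), with the contractile protein genes Tagln at 3.75 ± 0.328 and Acta2 at 2.71 ± 0.161. Connective tissue growth factor (Ccn2) rose by 3.69 ± 0.111 in a TGF-beta list with 7 of 13 up and 1 down (adjusted p = 0.0181, adjusted p = 0.147 with an estimated correlation). All 20 mitotic genes rose (adjusted p = 1.8e-07), with Mki67 at 2.62 ± 0.0669, and 12 of 23 replication genes rose (adjusted p = 0.000213), with the helicase gene Mcm3 at 2.34 ± 0.263. Immediate early genes had 11 of 16 up and 1 down (adjusted p = 0.000918), with Atf3 at 2.46 ± 0.312, Myc at 2.46 ± 0.133, Fos at 2.25 ± 0.148 and the phosphatase gene Dusp1 at -1.41 ± 0.0578.

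Metabolic lists were at their lowest medians at 16 weeks for bile acid, urea cycle and lipid synthesis genes. Bile acid synthesis and transport had 11 of 19 down with a median of -1.66 (adjusted p = 8.83e-11), with Cyp7a1 at -3.71 ± 0.0713. Urea cycle and amino acid catabolism had 21 of 27 down (adjusted p = 2.55e-17), with the proline oxidase gene Prodh at -2.42 ± 0.115. Lipogenesis and cholesterol synthesis had 19 of 24 down (adjusted p = 7.21e-15), with the isoprenoid enzyme gene Idi1 at -2.33 ± 0.0585 and the sterol demethylase gene Cyp51 at -2.31 ± 0.0456. Of 22 cytochrome P450 genes 17 fell and 1 rose (adjusted p = 1.36e-13), and Cyp2e1, which activates diethylnitrosamine, fell (-1.57 ± 0.0514). Pericentral Wnt targets had 8 of 10 down (adjusted p = 8.98e-05). Macrophage and Kupffer cell markers went both ways, with Gpnmb up (2.67 ± 0.0594), Clec4f, a Kupffer cell lectin gene, down (-2.14 ± 0.0444) and Cd5l down (-1.0 ± 0.0495, with another probe set at -0.88), and the list of 14 did not pass (median 0.18, adjusted p = 0.804). T and NK cell markers (adjusted p = 0.786) and endothelial markers (adjusted p = 0.952) did not pass either. Median centring gave 843 genes up and 1454 down at 16 weeks (36.7% up), against 72.1% up as deposited.

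At 18 weeks NRF2 targets and mitotic genes stayed above normal, and urea cycle, bile acid and P450 genes below it. Akr1b8 (6.95 ± 0.103), Aldh3a1 (6.95 ± 0.215), Bex1 (6.56 ± 0.308, with another probe set at 1.35), Pcp4 (6.49 ± 0.215), Ddit4l (6.0 ± 0.269) and the beta-defensin gene Defb1 (5.80 ± 0.350) had the largest rises. Obp3 (-7.08 ± 0.122), Cyp2c11 (-6.84 ± 0.131), Cpa1 (-5.71 ± 0.331), A1bg (-4.89 ± 0.115), the hydroxysteroid dehydrogenase gene Akr1c1 (-4.71 ± 0.112) and the hydroxyacid oxidase gene Hao2 (-4.24 ± 0.0752) had the largest falls. In total 1151 genes rose and 461 fell.

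NRF2 antioxidant targets had 15 of 17 up at 18 weeks (adjusted p = 1.47e-10), with Slc7a11 at 4.24 ± 0.186. Preneoplastic markers had 14 up and 1 down of 18 (adjusted p = 1.68e-06), with Gstp1 at 4.48 ± 0.0559 and Ggt1 at 3.60 ± 0.145, while Lcn2 fell (-1.20 ± 0.128). Mitotic genes had 19 of 20 up (adjusted p = 1.4e-07) and replication genes 13 of 23 (adjusted p = 1.71e-05), with cyclin E2 (Ccne2) at 2.69 ± 0.176. Among p53 targets 9 of 16 rose and 1 fell (adjusted p = 0.0014), with Cdkn1a at 4.26 ± 0.121. Matrix genes had 15 of 26 up (adjusted p = 3.18e-06), with Col1a1 at 2.77 ± 0.0872 (another probe set at 1.31), stellate cell and myofibroblast markers 5 of 12 (adjusted p = 0.0356, adjusted p = 0.0595 with an estimated correlation), cholangiocyte and progenitor markers 9 of 11 (adjusted p = 2.49e-06), with Sox4 at 4.17 ± 0.0484, and MHC class II genes 6 of 7 (adjusted p = 0.000431). Glycolysis genes had 5 of 16 up (adjusted p = 0.000439), with aldolase A (Aldoa) at 1.92 ± 0.0493. Among the lower lists were urea cycle and amino acid catabolism (15 of 27 down, adjusted p = 2.55e-17), cytochrome P450 genes (14 of 22 down, adjusted p = 8.12e-12), bile acid genes (10 of 19 down, adjusted p = 1.17e-09) and lipid synthesis genes (16 of 24 down, adjusted p = 1.4e-12). The estrogen sulfotransferase gene Sult1e1 fell (-3.62 ± 0.0575) and the glutathione transferase gene Gsta3 rose (2.71 ± 0.0636) in a list of 20 conjugating enzymes that went both ways, with 3 up and 4 down (adjusted p = 0.952). After median centring 55.0% of the calls were up, against 71.4% as deposited.

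**Figure D2:**
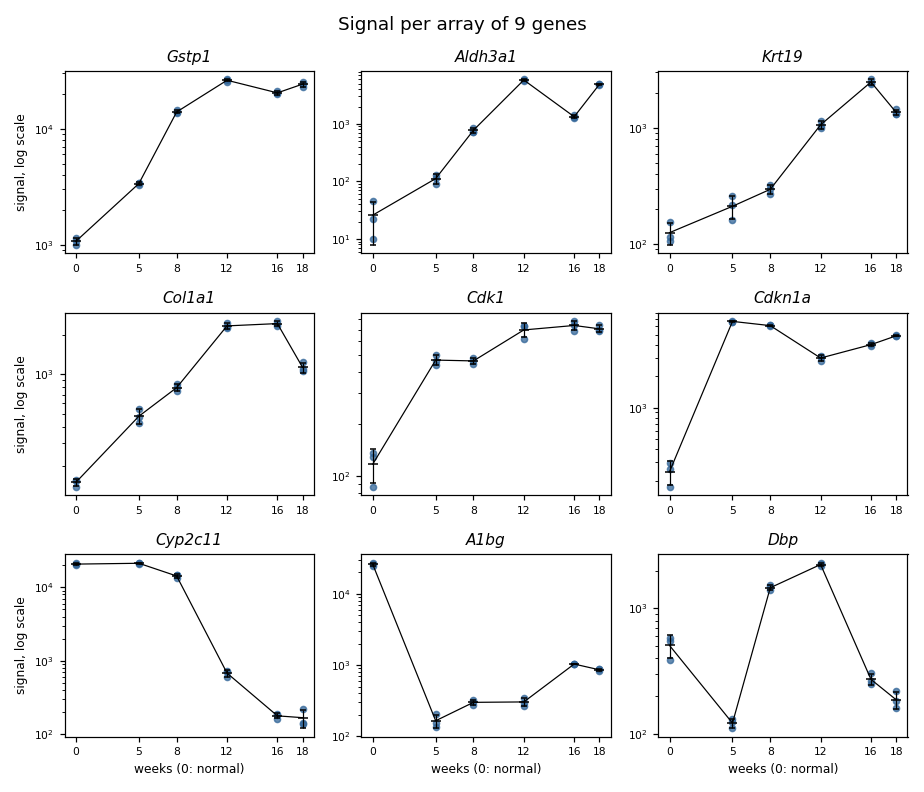
Signal (deposited scale, log axis) of 9 genes in normal liver and at each time of treatment, where dots are single arrays and bars are mean ± SD (n = 3). Gstp1 averaged 1069 in normal liver and 26105 at 12 weeks, and Cyp2c11 20718 in normal liver and 169 at 18 weeks.

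From 5 to 8 weeks 115 genes rose and 107 fell. With every probe set tested 175 rose and 372 fell. Akr1b8 rose by 3.09 ± 0.103 against 5 weeks, Bex1 by 3.54 ± 0.308, Slc7a11 by 2.53 ± 0.186 and Gstp1 by 2.04 ± 0.0559. The clock genes Nr1d1 (4.18 ± 0.122) and Dbp (3.42 ± 0.132) rose, where the labels give no hour of sampling, and the ficolin gene Fcnb (-3.35 ± 0.227), Cd14 (-3.32 ± 0.0706) and the cytokine signalling inhibitor gene Socs2 (-3.20 ± 0.230) fell. NRF2 targets had 6 of 17 up (adjusted p = 1.96e-07), and cytochrome P450 genes shifted down (median -0.37, adjusted p = 4.5e-08). The acute phase list had 1 gene up and 1 down (3 adjusted over the list alone, adjusted p = 1.4e-07, adjusted p = 0.0986 with an estimated correlation). For growth factors and receptors the median (0.01) and the direction of the test, which was down (adjusted p = 0.0189, adjusted p = 0.0507 with an estimated correlation), differed in sign. The Gapdh 3'/5' ratio was 1.48 at 5 weeks and 2.12 at 8 weeks, and a pseudocount of 64 gave 142 genes in place of 222.

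Between 8 and 12 weeks 476 genes rose and 194 fell, the largest step of the course. The 3'/5' ratios also moved most at this step, from 2.12 to 1.23 for Gapdh and from 4.48 to 2.69 for beta-actin. Star, which encodes the cholesterol carrier of steroid synthesis, rose by 4.47 ± 0.303, Abcc3 by 3.78 ± 0.307, Akr1b7 by 3.34 ± 0.0439, Aldh3a1 by 2.88 ± 0.215 and Igf2 by 2.5 ± 0.432. Obp3 (-4.71 ± 0.122), Cyp2c11 (-4.36 ± 0.131) and Cyp2a2 (-3.09 ± 0.0504), genes of male rat liver, had the largest falls. Preneoplastic markers had 11 of 18 up (adjusted p = 1.16e-06), cholangiocyte and progenitor markers 6 of 11 (adjusted p = 1.16e-06) and NRF2 targets 6 of 17 (adjusted p = 1.09e-10). Bile acid genes had 7 of 19 down (adjusted p = 1.1e-07), P450 genes 9 of 22 (adjusted p = 4.12e-08) and pericentral Wnt targets 5 of 10 (adjusted p = 0.00133). Mitotic genes, already above normal, did not pass as a list between these times (median 0.31, adjusted p = 0.0917). Median centring gave 35.4% of the calls up in place of 71.0%.

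The step from 12 to 16 weeks was smaller, with 95 genes up and 54 down. Aldh1a7 rose by 3.44 ± 0.0694 against 12 weeks, the secreted phospholipase gene Pla2g2a by 2.65 ± 0.118, Lilrb4 by 2.22 ± 0.526 and Krt19 by 1.21 ± 0.142. Mx2 (-5.81 ± 0.149), Dbp (-2.98 ± 0.132) and the steroid dehydrogenase gene Hsd17b2 (-2.71 ± 0.0456) fell, and another Mx2 probe set was called at no time. Aldh3a1 (-2.11 ± 0.215) and Gclc (-1.02 ± 0.0476) fell between these times, and the NRF2 list shifted down (median -0.51, adjusted p = 2.62e-09). Matrix genes (median 0.36, adjusted p = 3.51e-06), stellate cell and myofibroblast markers (median 0.59, adjusted p = 0.000318), cholangiocyte markers (median 0.70, 3 of 11 up, adjusted p = 0.00039) and erythroid and blood markers (median 0.60, 2 of 7 up, adjusted p = 8.64e-05) shifted up. B and plasma cell markers had 3 of 7 up (adjusted p = 0.0121, adjusted p = 0.0665 with an estimated correlation), with the immunoglobulin joining chain gene Jchain at 1.20 ± 0.0656. Median centring gave 48.9% of the calls up in place of 63.8%.

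From 16 to 18 weeks most changed genes were lower at the later time, 138 against 23 higher. Mx2 rose by 4.38 ± 0.149 against 16 weeks, the keratin gene Krt12 by 2.31 ± 0.284, the sulfotransferase gene Sult1c2 by 2.11 ± 0.0618 and Aldh3a1 by 1.86 ± 0.215. RT1-N3 (-3.49 ± 0.0949), Lcn2 (-3.28 ± 0.128), Lilrb4 (-2.93 ± 0.526) and Aqp5 (-2.06 ± 0.373) fell, and another RT1-N3 probe set shared none of its calls. Matrix genes had 7 of 26 down (adjusted p = 1.42e-12), with Col1a1 at -1.10 ± 0.0872, and stellate cell and myofibroblast markers 2 of 12 (median -0.52, adjusted p = 3.11e-05). B and plasma cell markers had 2 of 7 down (adjusted p = 0.00493), and mast cell markers, with 3 of 6 down, did not pass (adjusted p = 0.081), with Mcpt2 at -1.59 ± 0.335. Cholangiocyte markers shifted down (median -0.59, adjusted p = 0.00483) and lipid synthesis genes up (median 0.32, adjusted p = 4.5e-08). Complement and housekeeping genes had medians of 0.21 and 0.14 at this step and -0.11 and -0.10 at the step before. They passed at the preset correlation (adjusted p = 0.00301, 0.0418, 0.0105 and 0.0283) but not with an estimated correlation (adjusted p = 0.242, 0.348, 0.308 and 0.314). With quantile normalization the direction of these 4 tests reversed and none passed (adjusted p = 0.65, 0.364, 0.959 and 0.719). Median centring gave 70 genes up and 50 down (58.3% up) in place of 14.3% up, and a pseudocount of 64 gave 98 genes.

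Over the mean of the 5 treated groups, 954 genes were higher than in normal liver and 308 lower (75.6% up), and median centring gave 609 higher and 551 lower (52.5% up). Akr1b8 and Bex1 averaged 5.44 ± 0.0798 and 5.44 ± 0.239, Aldh3a1 5.05 ± 0.167, Cdkn1a 4.22 ± 0.0937, Tgfb1 3.91 ± 0.118, Gstp1 3.72 ± 0.0433 and Sox4 3.42 ± 0.0375. Another Bex1 probe set ranged from -0.98 at 5 weeks to 1.83 at 16 weeks. Cpa1 (-6.16 ± 0.256), A1bg (-5.88 ± 0.0894) and Obp3 (-4.47 ± 0.0942) had the lowest means among the named genes. Srd5a1, a steroid reductase gene, averaged -2.52 ± 0.0383 and Oat -2.45 ± 0.0920. In a comparison chosen after the data were seen, with each time reduced to its mean so that normal liver is 1 value against 5, 184 genes passed, 159 up and 25 down. The moderated F-test over the 6 groups called 3090 genes. In total 359 genes were changed in 1 direction at all 5 times (304 up, 55 down), among them Cdkn1a, Gstp1, Col1a1, Cdk1, Cd74, A1bg and Oat, and median centring gave 204 up and 98 down. Simulated unchanged groups, set against shared normal arrays that were simulated too, gave at most 0 such genes in 50 draws. The simulated noise had only the spread between arrays, so it cannot address a peculiarity of the real normal RNA. Independent lists of the observed sizes would share 0.0658 genes up and 0.000575 down. Part of the excess may come from the shared normal arrays, which at 3 arrays cannot be split between the comparisons. A further 22 genes were above normal at 1 time and below it at another.

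Set against 5 weeks, a reference chosen after the data were seen, 222 genes differed at 8 weeks, 968 at 12 weeks, 1212 at 16 weeks and 873 at 18 weeks. Of these, 146, 711, 979 and 648 were also changed in the same direction against normal liver. The rise of Bex1 and Akr1b8 from 5 to 8 weeks and the fall of Cyp2c11 and Obp3 from 8 to 12 weeks likewise do not rest on the normal arrays. In the mean of 12, 16 and 18 weeks against 5 weeks the preneoplastic list had a median of 2.11, cholangiocyte markers 2.13, NRF2 targets 1.74, bile acid genes -1.11 and P450 genes -1.04, while p53 targets had a median of 0.04.

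**Figure D3:**
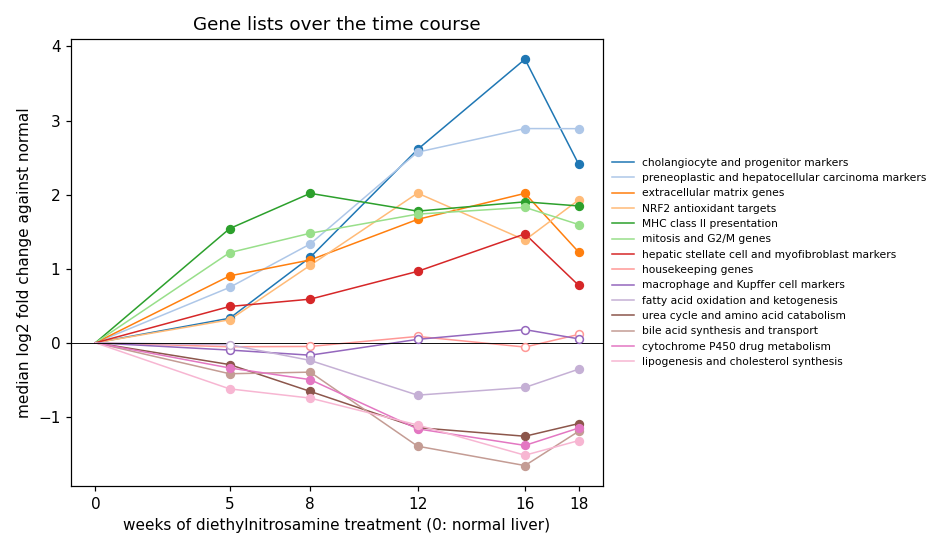
Median log2 fold change against normal liver of fixed gene lists at each time of treatment in weeks, with normal liver at 0, where filled points mark an adjusted p under 0.05 in camera and open points do not. Cholangiocyte and progenitor markers reach 3.83 at 16 weeks and bile acid synthesis and transport -1.66.

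A linear trend over weeks, fitted to the 6 group means so that the 3 arrays of a time count once, was found for 1411 genes, 968 rising and 443 falling. The fitted change over the course was 4.22 ± 0.705 for Ggt1, 4.13 ± 0.529 for Krt19, 3.33 ± 0.739 for Col1a1 and -8.29 ± 1.15 for Cyp2c11, with adjusted p = 0.0117, 0.00738, 0.0241 and 0.00761 in limma. The count was 281 with the treated times alone and 485 without the 16 week time, and other orders of the 6 times gave up to 1685 genes. After median centring 42.7% of the trends were rising, against 68.6% as deposited.

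Of 195 list tests against normal liver (39 lists at 5 times) 122 passed, 62 up and 60 down, and 98 passed with an estimated correlation. Of 156 tests against the previous time 77 passed, 32 up and 45 down, and 41 passed with an estimated correlation, while other groupings of the arrays gave up to 86. Lists such as those of T and NK cells, endothelial cells, adipocytes, muscle and circadian clock genes did not pass against normal liver at any time. Interferon response genes passed at 5 weeks (2 of 20 up, 1 down, adjusted p = 0.00711), with the chemokine gene Cxcl9 up (2.25 ± 0.0825) and Ifit1 down (-1.76 ± 0.239), and at no later time.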

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

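The tests of RNA integrity, of hepatocyte loss and a mixed-sex pool, and of a lower hepatocyte share were chosen only after the results were seen (that of hepatocyte loss after a comparison with male-biased genes had not passed and another had used all 9 female-biased genes), while the regroupings of arrays were set before, and the test of the hour of sampling was set after Dbp and Nr1d1 had been seen to differ but before the values of Tef, Bmal1 and Npas2 were.

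Of the named genes, 10 were changed above normal liver at 1 time and below it at another, so a difference of over 2 between these times follows from how they were picked, and a test of it in limma added nothing. The interferon-induced gene Mx2 differed by 5.81 (from -4.40 at 16 weeks to 1.41 at 12 weeks), while another Mx2 probe set shared no call with it. Star differed by 4.47 (from -1.31 at 8 weeks to 3.15 at 12 weeks). Nr1d1 differed by 4.18 (from -2.74 at 5 weeks to 1.45 at 8 weeks) and Dbp by 4.04 (from -1.90 at 5 weeks to 2.13 at 12 weeks). Of the neutrophil and myeloid cell genes RatNP-3b, Lcn2 and Fcnb, the first differed by 3.95 (from -2.93 at 18 weeks to 1.02 at 5 weeks), Lcn2 by 3.88 (from -1.80 at 8 weeks to 2.08 at 16 weeks) and Fcnb by 3.61 (from -2.04 at 8 weeks to 1.57 at 16 weeks). RT1-N3 differed by 3.68 (from -1.56 at 18 weeks to 2.11 at 8 weeks), with another probe set that shared no call. Aldh1a7 differed by 3.44 (from -1.49 at 12 weeks to 1.95 at 16 weeks) and Tgfbr2 by 2.93 (from -1.85 at 8 weeks to 1.07 at 12 weeks). Among 4722 tested probe sets with no gene name, which entered the comparisons above only where every probe set was tested, 411 were higher in the treated groups than in normal liver and 80 lower.

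Clock genes differed between times, where Hlf, also set in advance, did not pass the filter on signal. The mean log2 signal of Dbp, Nr1d1 and Tef, which peak late in the day, was 9.12 ± 0.143 in normal liver and 7.35 ± 0.200, 10.38 ± 0.0177, 10.58 ± 0.0242, 8.59 ± 0.0875 and 8.09 ± 0.0839 from 5 to 18 weeks (SD, n = 3). Over the 6 time means it ran against the mean of Bmal1 and Npas2, which peak in the opposite phase, with Pearson r = -0.866 (exact permutation p = 0.0111) and Spearman rho = -0.77 (exact permutation p = 0.103) over 720 orders, and r = -0.76 over the 4 times without 8 and 12 weeks. This is consistent with livers taken at different hours of the day, which the labels do not give, although Dbp and Nr1d1 had been seen to differ before the test and a clock changed by treatment stays open and untested. The tables argue against RNA integrity as the whole cause, since the first set differed by 1.99 ± 0.0908 (SD) between 12 and 16 weeks, where the Gapdh ratios were 1.23 and 1.26.

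Genes expressed mainly in female rat liver were high in the normal arrays, and at 5 weeks 9 such genes had a median change of -2.40, and 6 genes expressed mainly in male liver a median of -0.01. The tables argue against a general loss of hepatocyte expression as the whole cause at 5 weeks. The 118 genes of 9 hepatocyte lists, without the brightest and sex-biased ones, had a median of -0.19 (SD 0.741 over genes). Of these, 12 were called lower and 4 higher. Their median lay 1.75 above the median of -1.94 of the 4 female-biased genes in a list fixed before the data were examined, and 3 of the 118 fell as far. The permutation p of 0.00036 (100000 draws) carries no weight, since those 4 genes were sorted by sex only after values had been seen and genes are not independent replicates. The female-biased and male-biased medians differed by -2.40 with an exact permutation p of 0.0863, and several of the 9 female-biased genes were listed because they had been seen to fall, so a difference in sex stays open. If the normal RNA had held liver of both sexes in equal parts, male-biased genes would have risen by 5 weeks, but their median was -0.0074, and a pool cannot be told apart because 4 of the 6 were brighter than 99 percent of probe sets (a signal of 14196), where arrays may be saturated. A change of sex-dependent expression under treatment was not tested separately, and by 16 weeks all 6 male-biased genes were lower, with a median of -4.00.

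Most hepatocyte lists were lower and bile duct and matrix lists higher at the later times. A lower share of hepatocyte RNA alone would raise the genes of all other cell types by a single factor, but at 16 weeks the cholangiocyte median (3.83, 11 genes) exceeded the macrophage median (0.18, 14 genes) by 3.65. The permutation p of 8e-05 (100000 draws) carries no weight, since the list with the highest median was picked after it was seen. The macrophage list also held genes that fell, such as Clec4f. A lower share together with changes in other cell types stays open. The 3'/5' ratios were highest at 8 weeks, but bile duct and matrix lists lay further from normal liver at 16 weeks than at 8 weeks by at least 0.875 ± 0.0279 (SD). Lists of hepatocyte metabolism other than conjugating enzymes did so by at least 0.472 ± 0.0480 (fatty acid oxidation). This argues against integrity as the whole cause for these lists. Conjugating enzymes (0.157 ± 0.0370) cannot decide it, since the list passed against normal liver at no time and its mean was 0.14 at 8 weeks and -0.30 at 16 weeks. For 3 lists with secreted hepatocyte proteins integrity cannot be told apart, since the distance was 0.579 ± 0.0403 larger at 16 weeks for complement and coagulation but changed by 0.0440 ± 0.0547 for hepatocyte transcription factors and secreted proteins and by -0.453 ± 0.0535 for acute phase genes. A change in the number or in the expression of cells with bile duct markers stays open as a hypothesis, and the absence of untreated liver of matching age leaves age open too.

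Regrouping the arrays tested whether other groupings give as many calls. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one mixes arrays of both groups, which shrinks any difference and widens the spread within groups. Low counts for the other splits therefore follow from the design and carry no weight. The real splits gave 635, 1091, 1725, 2100 and 1612 genes from 5 to 18 weeks against normal liver, and the highest of the others 3, 1, 1, 0 and 0, with 1 split as large each time, the real one. For the steps the real splits gave 222, 670, 149 and 161 genes and the highest of the others 1, 0, 0 and 0, again with 1 split as large. All arrays were also regrouped in 100 groupings, drawn with the real one included. Only the real one was as large for all treated against normal (1262 genes, highest other 564, 1 as large) and the 6 groups (3090, highest other 1002, 1 as large). The same held for genes called at all 5 times (359, highest other 10, 1 as large) and lists against normal (122, highest other 113, 1 as large). Chance could not be excluded for lists against the previous time (77, highest other 86, 5 of 100 as large). For the trend 100 orders of the 6 times were taken in place of groupings of arrays, the real one included (1411, highest other 1685, 3 as large). The share lay under 0.05, but other orders gave as many genes or more, so chance in the order of the times is not excluded. The random groupings mix arrays of different times, so they carry real differences but also widen the spread within groups, which lowers their counts. The real grouping alone keeps the like arrays of a time together, so its larger counts do not exclude chance. These groupings, though not the orders of the times, move arrays that the labels call technical replicates, so they address only how arrays were assigned to groups, and chance differences between animals stay open.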

How the results depend on the processing

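Time means, the deposited log2 ratios, times without 8 weeks and 5 weeks as the reference were alternatives chosen after the data were seen, and the others were planned. The arrays, which the labels call technical replicates, limit what any alternative can show, and detection calls and background levels were not analysed here, so genes near the filter are the least certain. The planned use of the other deposited table was not run as a separate fit, since its treated values equal those used and its normal columns are in another order. Replicate numbers were not used as pairs. Residuals of the 45 same-number pairs correlated at -0.076 to 0.188 (mean 0.0433, against -0.0216 for other pairs), 9 of them above 0.1, and 9 of 18 arrays had their best match in their own number. Replicate 3 had the highest median signal of its group at all 5 treated times (142, 145, 174, 188 and 154), so a weak effect shared by a number is visible. A replicate block gave 636, 1087, 1727, 2099 and 1614 genes from 5 to 18 weeks.

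Counts moved by more than 1.5 times in these settings. Without a fold threshold they were 5295, 6228, 6903, 7183 and 6654 from 5 to 18 weeks against normal liver, 3774, 5286, 2898 and 4031 for the 4 steps, 7048 in all treated, 8885 over the groups and 2893 at all times, by construction larger. A fold threshold of 3 gave 187, 348, 718, 922 and 664, then 60, 193, 36 and 31 for the steps, 456, 1280 and 110, and 721 trends, by construction smaller. Testing every probe set gave 1388, 2351, 2984, 3775 and 2605, then 547, 1652, 236 and 521, 2184, 6110 and 604, with more probe sets tested. A pseudocount of 64 gave 402 at 5 weeks, 142 at 8 against 5 weeks, 98 at 18 against 16 weeks and 212 at all times, and no filter on low signals gave 279 at 18 against 16 weeks. The trend count was 281 with treated times only and 485 without 16 weeks. An estimated correlation left 41 lists shifted against the previous time. The time means gave 184 genes in all treated, and 5 weeks as the reference gave 222, 968, 1212 and 873 genes from 8 to 18 weeks. For pseudocount, filter and trend the cause was not tested.

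With quantile normalization the test of the complement list reversed direction while its median kept its sign, at -0.00649 for 16 against 12 weeks (from -0.11) and 0.0205 for 18 against 16 weeks (from 0.21), and neither test passed (adjusted p = 0.959 and 0.65). The housekeeping medians changed sign, to 0.0207 (from -0.10) and -0.000913 (from 0.14), and neither passed (adjusted p = 0.719 and 0.364). With the mean of a gene's probe sets Bex1 was at -0.15 at 5 weeks, where its other probe set was lower. The cause was not tested. Quantile normalization kept 526, 920, 1247, 1511 and 1318 calls in the same direction from 5 to 18 weeks, and median centring 526, 946, 1169, 1428 and 1323. The authors' deposited log2 ratios, averaged over pairs with no test, gave 682, 1108, 1690, 2090 and 1607 genes past 2-fold, with 515, 923, 1487, 1863 and 1414 called here in the same direction.

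Leaving out each array in turn gave 630 to 675 genes at 5 weeks, 1080 to 1140 at 8, 1705 to 1759 at 12, 2075 to 2138 at 16 and 1595 to 1634 at 18 weeks, 216 to 236, 653 to 709, 145 to 152 and 150 to 183 for the steps, 1243 to 1299 in all treated, 3064 to 3133 over the groups, 352 to 379 at all times, 1379 to 1417 trends, and 119 to 128 and 74 to 79 lists.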

Other observations

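The lists and tests in this part were fixed before the data were examined, but the time shown for each list was not set in advance. Chemokine and cytokine genes went both ways. Ccl2, which attracts monocytes, rose by 2.91 ± 0.155 at 16 weeks, Cxcl16 by 2.84 ± 0.0917 and Cx3cl1 by 1.79 ± 0.121. Cxcl12 (-2.32 ± 0.0511, with other probe sets at -0.43 and -1.77) and the alarmin gene Il33 (-2.13 ± 0.0649) fell, and the list of 15 did not pass at that time (adjusted p = 0.707). At 8 weeks, the only time it passed against normal liver, this list shifted down (median -0.27, 1 up and 2 down, adjusted p = 0.0262, adjusted p = 0.0479 with an estimated correlation, camera in limma). The list of growth factors, receptors and angiogenesis passed against normal liver only at 8 weeks. There it shifted down (median -0.30, 1 up and 4 down, adjusted p = 0.0254, adjusted p = 0.0461 with an estimated correlation, camera in limma). At 16 weeks the list went both ways, with 4 of 17 up and 5 down, and did not pass (adjusted p = 0.328). Its members Egfr, the epidermal growth factor receptor gene (-1.98 ± 0.0593, of whose 2 other probe sets 1 shared no call), and Ghr, the growth hormone receptor gene (-2.17 ± 0.0547), fell, and Angpt2, an angiogenesis gene, rose by 1.35 ± 0.177. The list of unfolded protein and amino acid stress genes shifted down at 12 weeks (median -0.17, 2 up and 2 down of 16, adjusted p = 0.0222). At this time Asns (1.17 ± 0.10) and Trib3 (1.06 ± 0.0872, with others at 1.30 and 0.80) rose. The endoplasmic reticulum genes Pdia4 (-1.50 ± 0.0841) and Edem1 (-1.17 ± 0.0418, whose 2 other probe sets shared no call) fell. The list did not pass at 5, 8, 16 and 18 weeks (adjusted p = 0.217, 0.13, 0.175 and 0.158, camera in limma).

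Erythroid and blood markers had 4 of 7 down at 12 weeks (adjusted p = 0.00304), with the haemoglobin genes Hbb at -1.62 ± 0.0488 and Hba-a2 at -1.24 ± 0.0519. This list also passed at 8 and 18 weeks (adjusted p = 0.017 and 0.0181, camera in limma) but not at 5 and 16 weeks (adjusted p = 0.169 and 0.111). Endothelial markers did not pass at 16 weeks (2 up and 2 down of 13, adjusted p = 0.952). The sinusoidal endothelial gene Stab2 (-1.26 ± 0.0941) and the vascular growth factor receptor gene Kdr (-1.36 ± 0.0741) fell at 16 weeks, and Vwf, a gene of larger vessels, rose by 1.64 ± 0.0902. The granzyme gene Gzma fell (-2.16 ± 0.135) and Blnk, an adaptor of B cell signalling, rose by 2.41 ± 0.194. T and NK cell markers and B and plasma cell markers passed as lists against normal liver at no time. The mesothelial gene Msln rose by 2.16 ± 0.173 and the lipoprotein lipase gene Lpl by 3.23 ± 0.0764. Adipocyte markers, which include Lpl, passed as a list at no time, and the mesothelial list, with 3 measured genes, was not tested. The complement genes C6 (-1.68 ± 0.0727) and C8a (-1.65 ± 0.0522) fell. Among 15 sex-biased hepatic genes 11 fell and 1 rose at 16 weeks (adjusted p = 2.31e-09), and the member that rose was the repressor gene Bcl6 (1.66 ± 0.145). In the pancreas list Cela1 fell (-1.78 ± 0.198) and Ctrc, another protease gene, rose by 1.84 ± 0.132 (list at 16 weeks with adjusted p = 0.0375, adjusted p = 0.118 with an estimated correlation). The pancreas list also passed at 8 weeks (adjusted p = 0.023, camera in limma) but not at 5, 12 and 18 weeks (adjusted p = 0.0622, 0.0507 and 0.0735).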
